A study of Rattus norvegicus with 16 samples.

How the data were processed

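The deposited table holds 30429 probes of an Affymetrix rat gene array for 16 samples of sorted carotid body cells from Wistar rats of 9 to 11 weeks. Per the labels, both carotid bodies were pooled and enzymatically dispersed, the cells were stained with an HNK-1 antibody, and HNK-1 positive cells were collected as neuroblasts and HNK-1 negative cells as glomus cells. The rats had breathed ambient air or had been in hypoxic chambers for 3 days. Biotinylated cDNA was made from 500 pg of total RNA per sample, and the labels name Transcriptome Analysis Console as the authors' tool. Its version, the background correction, the normalization between arrays and the array annotation are not given in the sources used here. The authors' values are on a log2 scale, which was inferred from their range of 0.87 to 13.33 and from the tool, since the deposited table does not state the base. All values have at most 2 decimals.

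The probe annotation names exactly 1 gene for 18511 probes, several genes for 575 and none for 11343. The single-gene probes name 18166 genes, of which 291 have more than 1 probe. The gene IDs of 18394 of the 18511 single-gene probes were found in the reference gene annotation, each with the same symbol. Genes are called by these symbols and probes by the numbers in the annotation. All probes were kept in every test, with no filter on dim probes and no further normalization. No array control probe is in the table.

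Samples formed 4 groups of 4 arrays, 2 populations by 2 oxygen conditions, as the labels name them. A linear model with 1 mean per group was fitted to each probe with limma 3.58.1 (lmFit and eBayes without intensity trend, 12 residual degrees of freedom) in R 4.3.3. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The 5 comparisons were neuroblasts minus glomus cells in normoxia and in hypoxia, hypoxic minus normoxic samples in glomus cells and in neuroblasts, and the interaction, which is the hypoxia difference in neuroblasts minus that in glomus cells. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all probes within a comparison, and a probe passed at an adjusted p under 0.05. Errors of differences are limma standard errors from the moderated variance, given after ±, and group values are means ± SD over 4 arrays. The labels do not say whether the samples of a group came from separate animals, so a p-value measures the spread between these samples only, and the number of arrays limits its precision.

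A total of 24 gene lists were fixed, each with 1 probe per gene (the one with the highest mean over all arrays). The lists were catecholamine synthesis and storage, dense-core granule and exocytosis, glomus cell oxygen sensing, glomus cell ion channels, sympathoadrenal transcription factors, neuroblast and immature neuron genes, cell cycle, glycolysis, other hypoxia-inducible factor targets, oxidative phosphorylation, cytosolic ribosomal proteins, immediate early and dissociation stress genes, endoplasmic reticulum stress, neurotransmitter and purinergic receptors, and HNK-1 epitope synthesis and carriers. Markers of other cell types formed 9 more lists: type II and glial cells, endothelial cells, pericytes and smooth muscle, fibroblasts, macrophages, T and NK cells, neutrophils, erythroid cells and peripheral neurons. Each list was tested against all other probes with camera from limma, with a preset correlation of 0.01, and adjusted over the 24 lists within a comparison. Camera with a correlation estimated for each list, and fry, which tests whether the genes of a list move on balance one way, were alternatives. For each list the genes that passed were counted with p-values adjusted over all probes and adjusted over the list alone.

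Genes to be named were chosen by rule. For the normoxic comparison of the populations and for each hypoxia comparison, these were the 10 largest rises and the 10 largest falls among probes that passed, whose 4 values of one group all lay above the 4 of the other, and which name 1 gene with an established symbol. For the hypoxic comparison of the populations the rule took 5 and 5, and for the interaction 5 and 5 without the condition on overlap. In each list, up to 4 genes with the smallest p were added, and B3gat1, Chst10, Th and Epas1 in every comparison. B3gat2, which the rule also held, was not measured by a single-gene probe. The lists, the rule, the tests and most alternatives were set before the data were examined. The counts of list genes that passed under other scalings and without hypoxic neuroblast replicate 1 were added after the arrays had been seen.

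The alternatives were centring each array on its median, quantile normalization, leaving out the dimmest 25% or the dimmer 50% of probes, an intensity trend with robust variance, array weights, fitting only the arrays compared, the replicate number as a block, averaging the probes of a gene, a fold threshold of 2, a stricter adjusted p of 0.01, and leaving out each array in turn. The fit was tested on simulated data with far fewer changed probes than passed for hypoxia, so the shares do not give the power there. With 100 probes changed 4-fold, 94% were recovered in each population comparison, 96% and 99% for hypoxia and 76% in the interaction. With 100 probes changed 2-fold these shares were 49% and 37%, 59% and 51%, and 13%. Gene families were tested in the same way after the data had been seen.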

Results

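The carotid body, the oxygen-sensing organ at the fork of the carotid artery, was profiled as 2 sorted cell populations of the rat. Glomus cells are its chemoreceptor cells, which store catecholamines, and neuroblasts are immature cells of the same neural crest lineage that carry the HNK-1 epitope, a sulfated sugar chain on neural adhesion molecules. Each population was taken from rats in ambient air (normoxia) and from rats after 3 days in hypoxic chambers, with 4 arrays per group. The mean of the array medians was 4.51 ± 0.10 in normoxic glomus cells, 4.52 ± 0.09 in normoxic neuroblasts, 4.72 ± 0.02 in hypoxic glomus cells and 4.80 ± 0.10 in hypoxic neuroblasts (log2, SD, n = 4). The first principal component, with 42.9% of the variance, parted the 8 hypoxic from the 8 normoxic arrays. Hypoxic neuroblast replicate 1 stood apart, with a mean correlation of 0.914 with the other arrays of its group across probes, against at least 0.949 for every other array. No label gives a date or batch of array processing, so such a batch and the oxygen condition cannot be told apart. Differences below are log2 with the standard error. Adjusted p-values are from limma or, for lists, from its camera test.

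**Figure D1:**
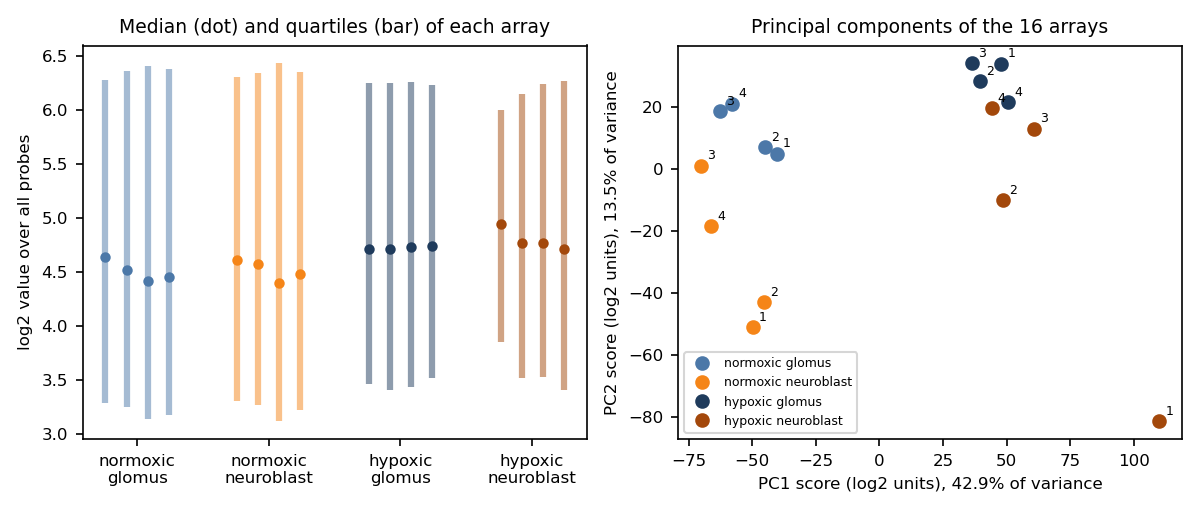
Left, median (dot) and quartiles (bar) of the log2 values over all probes for each array, by group. Right, scores of the 16 arrays on the first 2 principal components (42.9% and 13.5% of the variance), numbered by replicate, with hypoxic arrays on the right and hypoxic neuroblast replicate 1 apart from the rest.

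The comparison of neuroblasts with glomus cells in normoxia asks how the precursor-like cells differ from the mature chemoreceptor cells. Rbfox1 (probe 17653807), a neuronal splicing regulator, was at 8.99 ± 0.62 in neuroblasts and 4.66 ± 0.28 in glomus cells, a difference of 4.33 ± 0.27 (adjusted p = 3.12e-07). The sodium channel gene Scn9a differed by 4.20 ± 0.29, the A-type potassium channel gene Kcnd2 by 3.99 ± 0.30 and Dbh, which encodes the enzyme that turns dopamine into noradrenaline, by 3.74 ± 0.34 (adjusted p = 9.34e-06). Lower in neuroblasts were Cldn5 (probe 17671142), a tight junction protein of endothelial cells (-3.65 ± 0.34, adjusted p = 9.5e-06), Lgr5, a receptor of the Wnt pathway (-3.40 ± 0.25, adjusted p = 4.94e-07), and Adora2a, an adenosine receptor (-2.77 ± 0.41). Th, the rate-limiting enzyme of catecholamine synthesis, was at 12.62 ± 0.09 in glomus cells and 12.30 ± 0.19 in neuroblasts, a difference of -0.33 ± 0.39 (adjusted p = 0.972).

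By limma 555 of 30429 probes passed, 303 higher and 252 lower in neuroblasts, and 443 of them differed at least 2-fold. The groups did not overlap in 2250 of 30429 probes, where chance gives 2.86%, and in 521 of the 555. The other large differences included Prlh, which encodes prolactin-releasing hormone (3.58 ± 0.40), Epcam, an epithelial adhesion molecule (3.42 ± 0.43), and the secretin receptor gene Sctr (3.35 ± 0.27). Others were the synaptic vesicle gene Sv2c (3.32 ± 0.39), the glycosyltransferase gene Mgat4c (3.27 ± 0.34) and the cadherin gene Cdh7 (3.25 ± 0.30), all higher in neuroblasts. Lower in neuroblasts were Gpr139, an orphan receptor (-3.52 ± 0.41), the macrophage lysozyme gene Lyz2 (-2.83 ± 0.50) and the G protein subunit gene Gngt2 (-2.82 ± 0.30). So were Tac3, the neurokinin B precursor (-2.75 ± 0.36), Notum, a secreted Wnt inhibitor (-2.75 ± 0.29), Gnas, the stimulatory G protein subunit (-2.69 ± 0.28), and Hpcal1, a neuronal calcium sensor (-2.68 ± 0.41). A second probe of Gnas differed by -1.14 (adjusted p = 0.0529). For each of these and the genes above except Th, all 4 values of one population lay above all 4 of the other.

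The neuroblast and immature neuron list was higher in neuroblasts, with a median difference of 0.65 (list adjusted p = 3.2e-10, and adjusted p = 0.0746 with an estimated correlation). Of its 26 genes, 6 were higher and 2 lower, and 11 and 2 adjusted over the list alone. The microtubule regulators Stmn2 (1.52 ± 0.20) and Stmn4 (2.28 ± 0.35), the tubulin gene Tubb2b (2.17 ± 0.30) and the transcription factor gene Sox4 (1.44 ± 0.20) were higher, while a second probe of Tubb2b differed by 0.01. The 2 lower genes were Ret and Ntrk3, which encode growth factor receptors. Among the sympathoadrenal transcription factors, 2 of 14 were higher, Sox4 and Tbx20 (1.15 ± 0.16), and Gata3 was lower (-1.01 ± 0.24), with 2 and 1 adjusted over the list alone and no list call (list adjusted p = 0.106). Of the HNK-1 epitope list, B3gat1, a glucuronyltransferase that builds the epitope (1.36 ± 0.29, adjusted p = 0.0197), and its carrier L1cam (1.37 ± 0.32) were higher, 2 of 7 in both adjustments, and the sulfotransferase gene Chst10 differed by 0.04 ± 0.28 (list adjusted p = 0.0918). Of 29 receptor genes 6 were higher, among them the muscarinic receptors Chrm1 (1.55 ± 0.18) and Chrm3 (1.47 ± 0.19) and the GABA-B receptor gene Gabbr1 (1.43 ± 0.26), and 1 was lower, Adora2a, with 7 and 1 adjusted over the list alone. The receptor list's median was -0.02 (0.09 without normoxic glomus replicate 1, where the list passed with adjusted p = 0.0171) and its mean 0.15, with the test toward higher values (list adjusted p = 0.0614).

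Of 15 oxygen sensing genes 3 were lower, the mitochondrial subunits Cox4i2 (-1.19 ± 0.17) and Ndufa4l2 (10.45 ± 0.44 against 11.45 ± 0.17) and pyruvate carboxylase, Pc (-1.15 ± 0.26), and 4 adjusted over the list alone. The oxygen sensing median was -0.13 (list adjusted p = 0.00938, and adjusted p = 0.0746 with an estimated correlation). That median was -0.21 without normoxic neuroblast replicate 2 and -0.08 without replicate 3. Epas1, the oxygen-regulated transcription factor HIF-2α, differed by -0.25 ± 0.20 (adjusted p = 0.889). Of 22 dense-core granule genes 3 were lower, among them the granule proteins Chga (-1.26 ± 0.24) and Scg2 (-0.62 ± 0.14), with 1 higher and 6 lower adjusted over the list alone. The dense-core granule median was -0.20 (list adjusted p = 0.00168, and adjusted p = 0.336 with an estimated correlation). In the catecholamine list the vesicular transporter gene Slc18a1 was lower (-2.02 ± 0.29) and Dbh and the noradrenaline transporter gene Slc6a2 (2.15 ± 0.31) higher. Its 13 genes gave 2 higher and 3 lower adjusted over the list alone, a median of -0.29 (-0.12 without normoxic neuroblast replicate 2), a mean of 0.06 and a test toward lower values (list adjusted p = 0.409). Of 20 ion channels 3 were higher and 3 lower, including the potassium channels Kcnk3 (-1.74 ± 0.20) and Kcnj3 (-1.96 ± 0.33), with 6 and 6 adjusted over the list alone. That list's median was -0.03 (0.04 without normoxic glomus replicate 1), its mean 0.07 and its test toward higher values (list adjusted p = 0.814).

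Among the metabolic and stress lists, 1 of 15 glycolysis genes was lower in both adjustments, the phosphofructokinase gene Pfkp (-2.40 ± 0.29; list median -0.17, list adjusted p = 0.00938, and adjusted p = 0.336 with an estimated correlation). Of 28 other HIF targets Angpt2 was higher (1.34 ± 0.21) and 2, Vegfa (-1.21 ± 0.20) and Hmox1, were lower in both adjustments (list adjusted p = 0.506). The oxidative phosphorylation list had a median of -0.23, -0.13 without normoxic neuroblast replicate 1 (list adjusted p = 2.67e-05, and adjusted p = 0.336 with an estimated correlation), while the 1 of its 47 genes that passed, in both adjustments, was higher, Ndufa4 (0.62 ± 0.15). Of 22 immediate early genes Nr4a2 (1.39 ± 0.27) and Atf3 (1.63 ± 0.38), both transcription factors, were higher, with 3 adjusted over the list alone. The immediate early median was 0.16 (list adjusted p = 0.018, and adjusted p = 0.336 with an estimated correlation). That median was 0.24 without normoxic neuroblast replicate 1 and 0.07 without replicate 3. Of 20 endoplasmic reticulum stress genes limma passed 0, also adjusted over the list alone, and 2 had an unadjusted p under 0.05. The endoplasmic reticulum stress median was -0.20 (list adjusted p = 0.0106, and adjusted p = 0.336 with an estimated correlation). Limma also passed 0 of 32 cell cycle genes and 0 of 35 cytosolic ribosomal protein genes, in both adjustments, with 0 and 0 at an unadjusted p under 0.05 (list adjusted p = 0.107 for the first, list adjusted p = 0.409 for the second).

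Markers of other cell types moved with the sort. Macrophage markers were lower in neuroblasts, 7 of 15, and 14 adjusted over the list alone, with a median of -1.48 (list adjusted p = 4.2e-19, and adjusted p = 0.0746 with an estimated correlation). They included Lyz2, C1qb (-1.48 ± 0.27) and the receptor gene Csf1r (-2.13 ± 0.43). Endothelial markers had a median of -0.80, with Cldn5 lower among 11 genes and 8 lower adjusted over the list alone (list adjusted p = 7.96e-10, and adjusted p = 0.0773 with an estimated correlation). Among them Flt1 differed by -1.29 ± 0.40 (adjusted p = 0.157). Type II and glial cell markers were higher, with Gpm6b (2.04 ± 0.38) and Sostdc1 (1.53 ± 0.24) passing among 13 and 4 adjusted over the list alone. The glial median was 0.24 (list adjusted p = 0.00036, and adjusted p = 0.0746 with an estimated correlation). Fibroblast markers had a median of 0.72, 0.18 without normoxic neuroblast replicate 2 and 0.43 without normoxic glomus replicate 2, and 1 of 14 passed in both adjustments, Gsn (1.08 ± 0.26; list adjusted p = 0.000581, and adjusted p = 0.336 with an estimated correlation). Pericyte and smooth muscle markers had a median of 0.38, 0.03 without normoxic neuroblast replicate 2 and 0.59 without normoxic glomus replicate 1, and 1 of 10 passed, Mcam (2.54 ± 0.44), with 2 adjusted over the list alone (list adjusted p = 0.00532, and adjusted p = 0.336 with an estimated correlation). Cd4 was lower (-2.16 ± 0.51), 1 of 15 T and NK cell markers in both adjustments (list adjusted p = 0.19). The neurofilament gene Nefl was higher (1.63 ± 0.26), 1 of 15 peripheral neuron markers and 2 adjusted over the list alone (list adjusted p = 0.0581). Limma passed 0 of 11 neutrophil markers (median -0.02, 0.06 without normoxic neuroblast replicate 3, mean 0.02, list adjusted p = 0.791) and 0 of 6 erythroid markers (list adjusted p = 0.448), with 0 and 1 at an unadjusted p under 0.05.

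The count of 555 was 347 without normoxic glomus replicate 4, 348 without normoxic glomus replicate 3 and 353 without normoxic neuroblast replicate 1, and leaving out 1 array ended the calls of Ndufa4 (14 of the 16 fits, adjusted p up to 0.186 over all alternatives), Gsn (12, 0.152), L1cam (8, 0.0957), Gata3 (6, 0.141), Cd4 (6, 0.125), Scg2 (6, 0.119), Pc (6, 0.0906), Atf3 (4, 0.127), B3gat1 (without normoxic glomus replicate 3 or 4 or normoxic neuroblast replicate 3 or 4, 0.0901), Ndufa4l2 (3, 0.0756) and Csf1r (2, 0.0605). Without normoxic neuroblast replicate 2 the camera calls of the fibroblast (adjusted p = 0.112), pericyte (0.203) and immediate early lists (0.0629) ended, without normoxic neuroblast replicate 1 those of endoplasmic reticulum stress (0.218, median -0.07) and glycolysis (0.0534), and that of the immediate early list also without normoxic glomus replicate 2 (0.0866) or 4 (0.062) or normoxic neuroblast replicate 3 (0.125).

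**Figure D2:**
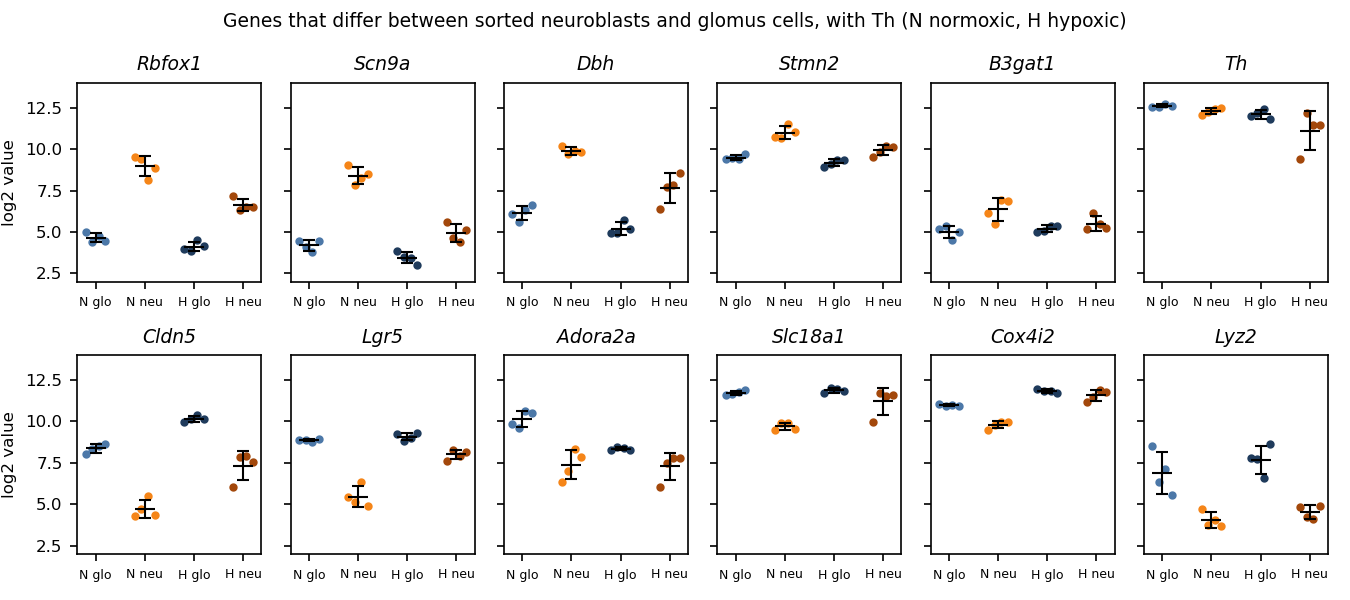
Log2 values of 12 genes on each array (dots) with the group mean and SD (bars), for normoxic (N) and hypoxic (H) glomus cells (glo) and neuroblasts (neu), 4 arrays per group. Rbfox1, Scn9a, Dbh, Stmn2 and B3gat1 were higher and Cldn5, Lgr5, Adora2a, Slc18a1, Cox4i2 and Lyz2 lower in normoxic neuroblasts, while Th differed by -0.33.

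The comparison of hypoxic with normoxic glomus cells asks how mature chemoreceptor cells respond to 3 days of low oxygen. Genes of the cell cycle were among the largest rises. Rrm2 (probe 17732584), the ribonucleotide reductase subunit needed for DNA synthesis, went from 5.88 ± 0.41 to 9.42 ± 0.16 (3.54 ± 0.23, adjusted p = 2.09e-07), and the kinase gene Cdk1 and its partner gene Cks2 rose by 3.09 ± 0.32 and 3.28 ± 0.19. Npy, the neuropeptide Y gene, rose by 2.34 ± 0.20, Tac3 by 2.77 ± 0.36 and Gch1, which makes the cofactor of tyrosine hydroxylase, by 2.18 ± 0.27. Among the named genes the largest fall was that of Sstr1 (probe 17816003), a somatostatin receptor (-3.38 ± 0.42, adjusted p = 4.98e-05), and the transcription factor gene Epas1 went from 12.74 ± 0.04 to 11.16 ± 0.18 (-1.58 ± 0.20, adjusted p = 5.23e-05).

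By limma 5744 probes passed (18.9% of all), 2852 higher and 2892 lower in hypoxia, 2760 of them at least 2-fold. The groups did not overlap in 8045 probes and in 5169 of the 5744. The median of all probes was 0.17 higher in hypoxia. With each array centred on its median 1370 probes passed as higher and 3783 as lower, and with quantile normalization 2215 and 2490, so list medians are also given after centring. The other large rises were those of the calcium-binding proteins S100a10 (3.58 ± 0.40) and S100a11 (3.37 ± 0.47), Pf4, a chemokine of platelets and macrophages (3.30 ± 0.58), the imprinted neuronal gene Nnat (2.91 ± 0.27), the cell cycle phosphatase gene Cdkn3 (2.64 ± 0.40) and Sap18 (2.62 ± 0.34). A second probe of Rrm2 differed by 0.28 (adjusted p = 0.44), and one of Nnat rose by 2.08. Falls included the adenylate cyclase gene Adcy1 (-2.54 ± 0.25), the stem cell surface gene Prom1 (-2.44 ± 0.20), Arhgap36 (-2.96 ± 0.41), Tmem161a (-2.85 ± 0.35), and Irf2bpl (-2.84 ± 0.36). Also lower were Rtfdc1 (-2.52 ± 0.24), the Rab regulators Ankrd27 (-2.51 ± 0.25) and Tbc1d13 (-2.48 ± 0.27), and the olfactory receptor gene Or2ak5 (-2.44 ± 0.36). For each of these genes all 4 values of one condition lay above all 4 of the other.

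Of 32 cell cycle genes 14 rose and 0 fell, and 20 rose adjusted over the list alone. The cell cycle median was 0.75 (centred 0.53, list adjusted p = 8.12e-08, and adjusted p = 0.108 with an estimated correlation). Besides Rrm2 and Cdk1 they included the proliferation marker Mki67 (2.58 ± 0.27) and the DNA clamp Pcna (1.52 ± 0.15). Macrophage markers rose beside them, 5 of 15 and 6 adjusted over the list alone, with a median of 0.76, 1.31 without normoxic glomus replicate 1 and 0.40 without replicate 4 (centred 0.54, list adjusted p = 0.019, and adjusted p = 0.668 with an estimated correlation). Aif1 (2.18 ± 0.37), Tyrobp (1.89 ± 0.30) and C1qc (1.49 ± 0.23) were among them. Of 47 oxidative phosphorylation genes 29 rose and 0 fell, and adjusted over the list alone 31 rose and 4 fell. The oxidative phosphorylation median was 0.75 (centred 0.53, list adjusted p = 8.12e-08, and adjusted p = 0.407 with an estimated correlation). The subunits Uqcrq (1.50 ± 0.19), Cox5a (1.20 ± 0.17) and Ndufb3 (0.96 ± 0.14) were examples. Of 35 ribosomal protein genes 11 rose and 1 fell, and 15 and 1 adjusted over the list alone, with Rps16 (1.64 ± 0.19) and Rplp2 (0.95 ± 0.15) among the rises. The ribosomal protein median was 0.43 (centred 0.21, list adjusted p = 0.00153, and adjusted p = 0.409 with an estimated correlation).

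Genes of the chemoreceptor and neuronal phenotype fell in several lists. Of 20 ion channels 2 rose and 6 fell, and 2 and 8 adjusted over the list alone. The ion channel median was -0.48 (centred -0.69, list adjusted p = 0.000649, and adjusted p = 0.108 with an estimated correlation). The calcium-permeable channel Trpc5 (-2.02 ± 0.19) and the potassium channels Kcnq3 (-1.46 ± 0.20) and Kcnk9 (-1.53 ± 0.22) were among the falls. Of 14 sympathoadrenal transcription factors 6 fell, and 7 adjusted over the list alone, including Isl1 (-1.43 ± 0.27) and Tbx20 (-0.75 ± 0.16). The transcription factor median was -0.50 (centred -0.72, list adjusted p = 0.00118, and adjusted p = 0.164 with an estimated correlation). Of 26 neuroblast and immature neuron genes 6 fell, and 7 adjusted over the list alone, with the axon guidance genes Dpysl3 (-1.84 ± 0.26) and Crmp1 (-1.20 ± 0.28) among them. The immature neuron median was -0.23 (centred -0.44, -0.14 without normoxic glomus replicate 3, list adjusted p = 0.00285, and adjusted p = 0.407 with an estimated correlation). Of 22 dense-core granule genes 2 rose and 6 fell, and 2 and 7 adjusted over the list alone, such as Ptprn2 (-1.59 ± 0.22), the calcium sensor of exocytosis Syt1 (-1.18 ± 0.17) and the priming factor Unc13b (-1.74 ± 0.25). The dense-core granule median was -0.12 (centred -0.34, list adjusted p = 0.00285, and adjusted p = 0.408 with an estimated correlation). That median was -0.21 without normoxic glomus replicate 1 and -0.06 without replicate 4. The catecholamine list split, with Gch1, Pts and Spr (0.94 ± 0.17), which make the cofactor tetrahydrobiopterin, rising and Ddc, Slc6a2 (-1.35 ± 0.31) and the catecholamine-degrading enzyme gene Maoa (-1.44 ± 0.25) falling, and 4 and 4 of 13 adjusted over the list alone (list adjusted p = 0.573). Th differed by -0.52 ± 0.39 (adjusted p = 0.38).

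The hypoxia and stress lists were mixed. Of 28 other HIF targets 3 rose, among them the mitochondrial gene Higd1a (1.14 ± 0.19), and 3 fell, namely the vasodilator peptide gene Adm (-1.46 ± 0.26), the carbonic anhydrase gene Car12 (-1.97 ± 0.28) and Ndrg1 (-1.28 ± 0.17), with 3 and 4 adjusted over the list alone. The median was 0.22, the mean 0.09 and the centred median 0.005, with the test toward lower values (list adjusted p = 0.991). Of 15 oxygen sensing genes Cox4i2 and Egln1 rose and 4 fell, Epas1, Pc (-1.69 ± 0.26), Rgs4 (-1.13 ± 0.18) and Rgs5, and 2 and 5 adjusted over the list alone. Their median was 0.16 (0.10 without normoxic glomus replicate 3), the mean -0.17 and the centred median -0.05, with the test toward lower values (list adjusted p = 0.152). Of 15 glycolysis genes the lactate exporter Slc16a3 rose (0.90 ± 0.22) and 3 fell, the glucose transporter Slc2a3 (-1.74 ± 0.39), Pfkfb3 and Pfkfb4, with 1 and 4 adjusted over the list alone (list adjusted p = 0.0923). Of 22 immediate early genes 2 rose and 7 fell, in both adjustments, including Jun (-1.61 ± 0.27; its second probe differed by -0.78, adjusted p = 0.0817) and Dusp1 (-1.78 ± 0.32). The immediate early median was -0.25 (centred -0.46, list adjusted p = 0.00494, and adjusted p = 0.407 with an estimated correlation). That median was -0.39 without normoxic glomus replicate 4 and -0.16 without hypoxic glomus replicate 4. Of 20 endoplasmic reticulum stress genes 2 rose, with Trib3 (1.06 ± 0.24), and 8 fell, with the chaperone gene Calr (-1.85 ± 0.21) and Herpud1 (-1.17 ± 0.19), in both adjustments. The endoplasmic reticulum stress median was -0.37 (centred -0.58, -0.23 without hypoxic glomus replicate 2, list adjusted p = 0.00229, and adjusted p = 0.407 with an estimated correlation).

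Of 29 receptors Adora1 rose and 4 fell in both adjustments, among them the nicotinic receptor Chrna7 (-2.06 ± 0.23) and Adora2a (-1.82 ± 0.41), while the median of 0.16 (0.24 without normoxic glomus replicate 1) had the opposite sign to the mean (-0.07) and turned to -0.06 after centring, with the test toward lower values (list adjusted p = 0.594). L1cam (-1.32 ± 0.32) and Ncam1 fell among the 7 HNK-1 genes, and 3 adjusted over the list alone, while Chst10 differed by -0.70 ± 0.28 and B3gat1 by 0.19 ± 0.29 (list adjusted p = 0.0918). Among the markers of other cells, S100b rose (1.93 ± 0.41) and Cdh19 and Mbp fell of 13 glial genes, with 2 and 2 adjusted over the list alone (list adjusted p = 0.991). In both adjustments Cldn5 (1.77 ± 0.34) and Emcn rose of 11 endothelial genes (list adjusted p = 0.529) and Des and Myl9 of 10 pericyte genes (list adjusted p = 0.448). So did Cd3g (1.32 ± 0.31) of 15 T and NK genes (list adjusted p = 0.38) and Npy of 15 peripheral neuron genes (list adjusted p = 0.444). Fbln1 fell (-1.08 ± 0.22) of 14 fibroblast genes in both adjustments. The fibroblast median was 0.27 (0.13 without normoxic glomus replicate 2, mean 0.12, test toward lower values, list adjusted p = 0.612). Limma passed 0 of 11 neutrophil (list adjusted p = 0.454) and 0 of 6 erythroid markers (list adjusted p = 0.57), with 3 and 1 at an unadjusted p under 0.05. After centring, the medians of the glial (-0.06), T and NK (-0.00), neutrophil (-0.02) and peripheral neuron lists (-0.04), positive before, were negative.

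The macrophage list's camera call ended without normoxic glomus replicate 2 (adjusted p = 0.132) or 4 (0.112), and that of the immediate early list without hypoxic glomus replicate 4 (0.0568). Each named gene that passed kept its call under each of the 22 alternatives run on it.

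**Figure D3:**
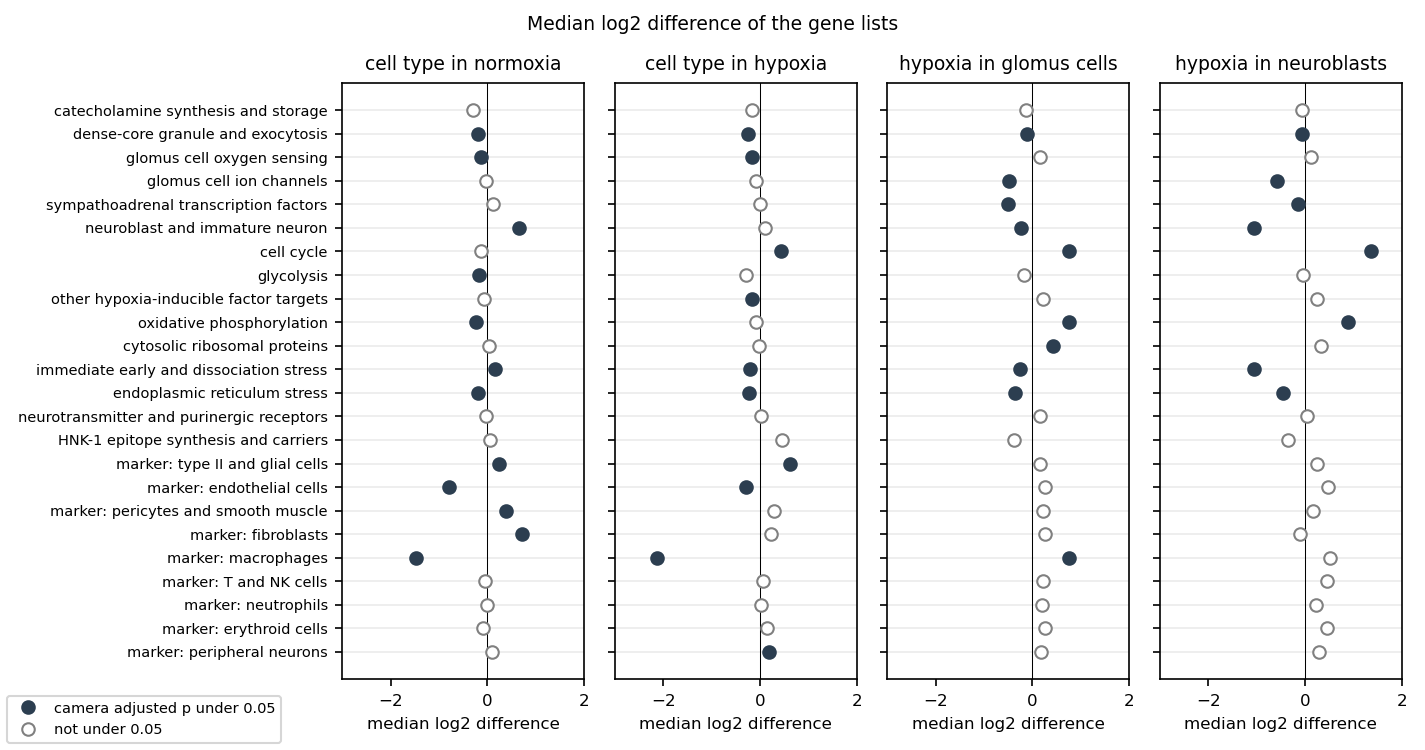
Median log2 difference of each of the 24 gene lists in 4 comparisons (neuroblasts minus glomus cells, or hypoxic minus normoxic), with filled dots where the camera adjusted p at a preset correlation was under 0.05. The cell cycle list had medians of 0.75 and 1.37 in the hypoxia comparisons and the macrophage list medians of -1.48 and -2.13 between the populations.

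The comparison of hypoxic with normoxic neuroblasts asks the same question for the immature cells. Among the largest rises were again those of cell division genes. Cdkn3 (probe 17697904) went from 4.31 ± 0.55 to 9.18 ± 0.12 (4.88 ± 0.40, adjusted p = 5.49e-07), Rrm2 rose by 4.80 ± 0.23, Cdk1 by 4.51 ± 0.32 and Mki67 by 3.62 ± 0.27. Several genes that were higher in normoxic neuroblasts fell, among them Kcnd2 (-3.47 ± 0.30), Scn9a (-3.46 ± 0.29), Cdh7 (-3.38 ± 0.30) and Sctr (-3.19 ± 0.27). Dbh went from 9.90 ± 0.22 to 7.64 ± 0.90 (-2.27 ± 0.34, adjusted p = 0.000108) and Th fell by 1.17 ± 0.39 (adjusted p = 0.03), by 0.59 without hypoxic neuroblast replicate 1.

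By limma 9755 probes passed (32.1% of all), 5596 higher and 4159 lower, 4251 of them at least 2-fold. The groups did not overlap in 8511 probes and in 7269 of the 9755. The median of all probes was 0.25 higher in hypoxia and their SD lower (1.97 against 2.15). After centring 1826 passed as higher and 5464 as lower, after quantile normalization 3278 and 3701. The order of the populations by count was not stable. Fits of only the arrays compared gave 6262 probes here and 7435 in glomus cells, and array weights gave 8248 and 9490. Without hypoxic neuroblast replicate 1 the counts were 8074 and 7232. These counts thus do not rank the responses. Other large rises were those of the mitotic genes Pbk (4.20 ± 0.32), Cks2 (3.84 ± 0.19), Pttg1 (3.74 ± 0.35) and Nusap1 (3.64 ± 0.22), of Tac3 (3.88 ± 0.36) and of S100a10 (3.70 ± 0.40). Falls included the redox regulator Txnip (probe 17741001, -3.56 ± 0.49), Scube1 (-3.36 ± 0.29), the nuclear import factor Tnpo1 (-3.35 ± 0.39), the RNA helicase gene Ddx6 (-3.30 ± 0.33), the axonal adhesion gene Nfasc (-3.25 ± 0.24) and Car12 (-3.15 ± 0.28). A second probe of Rrm2 rose by 0.89 (adjusted p = 0.0108). All 4 values of one condition lay above all 4 of the other for each gene named so far in this comparison except Th.

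Of 32 cell cycle genes 23 rose and 0 fell, and 25 rose adjusted over the list alone. The cell cycle median was 1.37 (centred 1.08, list adjusted p = 7.42e-11, and adjusted p = 0.069 with an estimated correlation). Macrophage markers gave 0 of 15 that passed by limma and 1 at an unadjusted p under 0.05, with Fcer1g at 0.81 ± 0.40. The macrophage median was 0.52 (centred 0.24, list adjusted p = 0.38). Of 47 oxidative phosphorylation genes 32 rose and 4 fell, and 33 and 5 adjusted over the list alone. The oxidative phosphorylation median was 0.89 (centred 0.60, list adjusted p = 1.97e-06, and adjusted p = 0.43 with an estimated correlation). Ndufb6 (2.41 ± 0.27) and Uqcrq (2.22 ± 0.19) rose, and the falls were Ndufs1, Sdha and the ATP synthase subunits Atp5f1a and Atp5f1b. Of 35 ribosomal protein genes 12 rose, with Rps16 (1.76 ± 0.19), and 2 fell, and 12 and 3 adjusted over the list alone. Their median of 0.32 became 0.04 after centring, with no list call (list adjusted p = 0.131), though adjusted p = 0.00986 without hypoxic neuroblast replicate 1.

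Genes of immature neurons fell. Of 26 such genes 15 fell and 2 rose, the growth cone gene Gap43 and Ret, and 17 and 4 adjusted over the list alone. The immature neuron median was -1.04 (centred -1.33, list adjusted p = 1.67e-06, and adjusted p = 0.169 with an estimated correlation). Dpysl3 (-2.40 ± 0.26), Sox4 (-2.22 ± 0.20) and L1cam (-2.04 ± 0.32) were among the falls. Of 14 sympathoadrenal transcription factors 5 fell, including Isl1 (-2.32 ± 0.27) and Tbx20 (-1.79 ± 0.16), and Hand1 rose, in both adjustments. The transcription factor median was -0.13 (centred -0.42, list adjusted p = 0.00317, and adjusted p = 0.169 with an estimated correlation). Leaving out single arrays moved that median between -0.27 (hypoxic neuroblast replicate 4) and -0.05 (hypoxic neuroblast replicate 1), and to -0.25 without normoxic neuroblast replicate 1 and -0.07 without replicate 3. Of 20 ion channels 3 rose and 11 fell, with the calcium channel Cacna1b (-1.81 ± 0.20) and the potassium channel Kcnma1 (-1.40 ± 0.20), and 4 and 11 adjusted over the list alone. The ion channel median was -0.59 (centred -0.87, list adjusted p = 0.000755, and adjusted p = 0.0944 with an estimated correlation). Of 29 receptors 6 rose and 8 fell, among them Chrna7 (-3.04 ± 0.23) and Gabbr1 (-2.58 ± 0.26), and 7 and 8 adjusted over the list alone. The receptor median was 0.04 (0.00 without normoxic neuroblast replicate 1 and 0.09 without hypoxic neuroblast replicate 2), the mean -0.21 and the centred median -0.25, with the test toward lower values (list adjusted p = 0.188). Of 7 HNK-1 genes 2 rose and 3 fell in both adjustments, with B3gat1 among the falls (-0.86 ± 0.29, adjusted p = 0.0346) and Chst10 at -0.26 ± 0.28 (list adjusted p = 0.131).

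Of 22 dense-core granule genes 2 rose, with Vgf (1.49 ± 0.26), and 9 fell, with Unc13b (-2.22 ± 0.25), in both adjustments. The dense-core granule median was -0.06 (centred -0.35, list adjusted p = 0.013, and adjusted p = 0.508 with an estimated correlation). That median was between -0.11 and -0.15 without normoxic neuroblast replicate 2 or 3 or hypoxic neuroblast replicate 2 or 3. Of 13 catecholamine genes 4 rose, with Gch1 (2.29 ± 0.27), and 5 fell, with Slc6a2 (-2.52 ± 0.31), Dbh and Th, and 6 and 6 adjusted over the list alone (list adjusted p = 0.398). Of 15 oxygen sensing genes 3 rose, with Cox4i2 (1.78 ± 0.17), and 5 fell, with Epas1 (-1.96 ± 0.20), and 4 and 5 adjusted over the list alone. The oxygen sensing median was 0.12 (-0.02 without hypoxic neuroblast replicate 1 and 0.19 without normoxic neuroblast replicate 1, mean -0.12, centred -0.16, test toward lower values, list adjusted p = 0.273). Of 28 other HIF targets 6 rose, with Higd1a (1.12 ± 0.19), and 7 fell, with Ndrg1 (-1.62 ± 0.17) and Adm (-1.71 ± 0.26), and 8 and 7 adjusted over the list alone. The HIF target median was 0.24 (mean -0.03, centred -0.04, test toward lower values, list adjusted p = 0.441). Of 15 glycolysis genes 3 rose, with the kinase gene Pgk1 (0.94 ± 0.20), and 3 fell, with Slc2a3 (-2.40 ± 0.39), and 3 and 4 adjusted over the list alone (list adjusted p = 0.369). Immediate early genes fell, 14 of 22 with 1 rise, Ier3, and 15 and 1 adjusted over the list alone, including Dusp1 (-2.92 ± 0.32), Jun (-2.73 ± 0.27) and Fosb (-2.58 ± 0.27). The immediate early median was -1.06 (centred -1.34, list adjusted p = 1.66e-07, and adjusted p = 0.132 with an estimated correlation). Of 20 endoplasmic reticulum stress genes 10 fell, with Herpud1 (-1.85 ± 0.19) and the chaperone gene Hspa5 (-1.06 ± 0.21), and 2 rose, in both adjustments. The endoplasmic reticulum stress median was -0.46 (centred -0.74, list adjusted p = 0.00265, and adjusted p = 0.43 with an estimated correlation).

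Among markers of other cells, 3 of 13 glial genes rose, with S100b (2.33 ± 0.41) and Gfap (0.87 ± 0.17), and Prnp fell, in both adjustments (list adjusted p = 0.691). Of 11 endothelial genes 2 rose in both adjustments, Cldn5 (2.60 ± 0.34) and Vwf (list adjusted p = 0.134), and of 10 pericyte genes Des and Myl9 (1.46 ± 0.32; list adjusted p = 0.876). Of 14 fibroblast genes Fbln2 rose and Fbln1 and Gsn (-1.03 ± 0.26) fell in both adjustments (list adjusted p = 0.131). Rises were passed by 4 of 15 T and NK genes in both adjustments, with Cd3g (1.25 ± 0.31; list adjusted p = 0.113). They were also passed by 2 of 6 erythroid genes, the globins Hba-a1 (1.44 ± 0.37) and Hbb-b1 (1.17 ± 0.36), with 4 adjusted over the list alone (list adjusted p = 0.134). Of 15 peripheral neuron genes 4 rose, with Npy (2.68 ± 0.20), and 2 fell, Nefl and Snap25, and 6 and 3 adjusted over the list alone (list adjusted p = 0.42). Limma passed 0 of 11 neutrophil genes and 2 had an unadjusted p under 0.05 (list adjusted p = 0.452). After centring, the medians of the glial (-0.03), pericyte (-0.12) and neutrophil lists (-0.05), positive before, were negative.

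Leaving out 1 array ended the calls of B3gat1 (without normoxic neuroblast replicate 3 or 4 or hypoxic neuroblast replicate 1, 3 or 4, adjusted p up to 0.114 over all alternatives), Th (without normoxic neuroblast replicate 3 or 4, 0.0698) and Hbb-b1 (3 of the 16 fits, 0.0658), quantile normalization that of Gsn (0.0814), and without hypoxic neuroblast replicate 1 the dense-core granule list missed the threshold (adjusted p = 0.0545). Quantile normalization ended the camera calls of the dense-core granule (0.178) and endoplasmic reticulum stress lists (0.128) and gave one to the ribosomal list (0.0221).

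**Figure D4:**
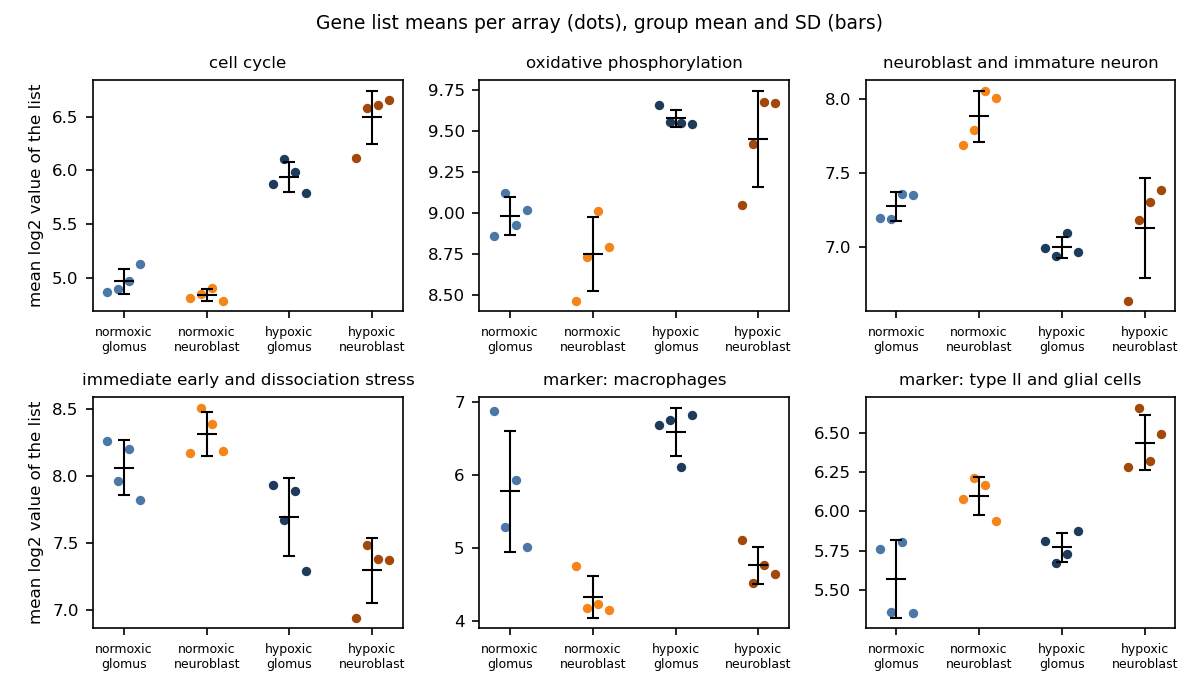
Mean log2 value of 6 gene lists on each array (dots) with the group mean and SD (bars), 4 arrays per group. Cell cycle and oxidative phosphorylation means were higher on all hypoxic than on all normoxic arrays of a population, and macrophage means were lower in neuroblasts than in glomus cells of the same oxygen condition.

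The differences between hypoxic and normoxic arrays overlapped between the populations. Rrm2, Cks2, Cdk1, Mki67, Cdkn3, Tac3, Npy and Gch1 rose in both, and Epas1, Car12, Ndrg1, Adm, Jun, Dusp1 and Chrna7 fell in both. Across all probes, which are not independent replicates, the differences in glomus cells and neuroblasts had a Pearson r of 0.807 and a Spearman rho of 0.708, with a jackknife standard error of 0.037 for r over the arrays. Probes that passed in both numbered 4463, with 2028 higher in both, 2430 lower in both and 5 opposite, where 524.5 and 395.3 would be higher or lower in both if the calls were independent. After leaving out the dimmer 50% of probes r was 0.856.

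**Figure D5:**
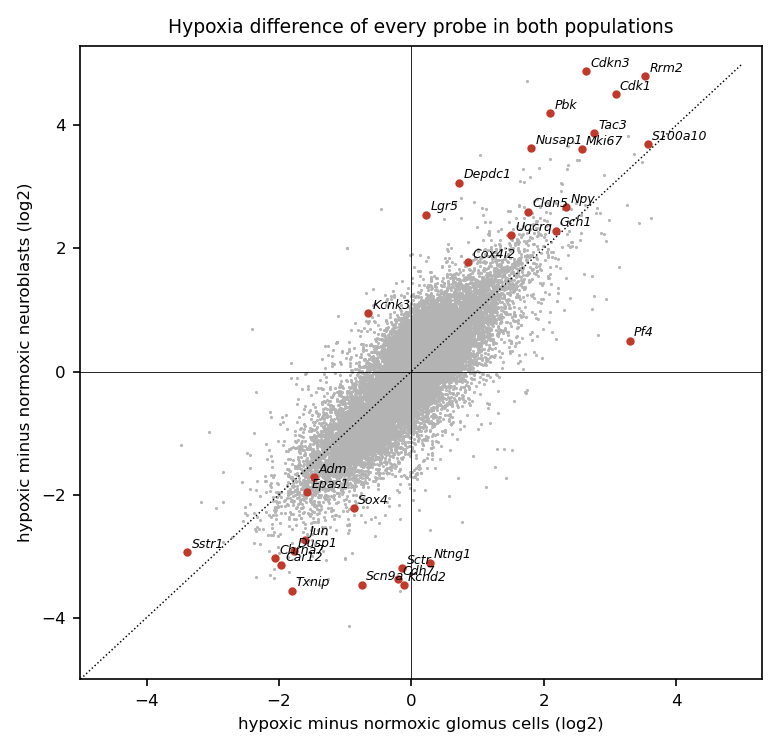
Each dot is a probe, with the log2 difference of hypoxic minus normoxic glomus cells (horizontal) against that of neuroblasts (vertical), and named genes in red. The dotted line marks equal differences, and Kcnd2, Cdh7 and Sctr fell in neuroblasts while lying near 0 in glomus cells (-0.12 for Kcnd2).

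The comparison of the populations in hypoxia asks which differences remain. Rbfox1 (2.51 ± 0.27), Prlh (2.67 ± 0.40), Mgat4c (2.63 ± 0.34) and Dbh (2.44 ± 0.34, adjusted p = 0.00348) were again higher in neuroblasts, and Scn9a differed by 1.49 ± 0.29. Acot1, an acyl-CoA thioesterase gene, was higher as well (2.54 ± 0.40). Cldn5 (-2.82 ± 0.34) and the myeloid genes Pf4 (-4.62 ± 0.58, adjusted p = 0.00149), Cd74 (-4.22 ± 0.66), Lyz2 (-3.15 ± 0.50) and Fcer1g (-2.99 ± 0.40) were lower. By limma 86 probes passed, 42 higher and 44 lower, 81 of them at least 2-fold. The groups did not overlap in 1364 of 30429 probes, where chance gives 2.86%, and in 85 of the 86. After median centring 28 passed as higher and 48 as lower, after quantile normalization 79 and 72, and without hypoxic neuroblast replicate 1 72 and 47. Of the 555 probes that passed in normoxia, 492 (88.6%) had the same sign in hypoxia, and 46 passed in both, 19 higher and 27 lower, where 0.4 and 0.4 would do so if the calls were independent. Across all probes the 2 sets of differences had a Pearson r of 0.363 and a Spearman rho of 0.219 (jackknife standard error of r 0.093).

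The lists with calls that held with an estimated correlation were those of the cell cycle, of type II and glial cells and of macrophages. Cell cycle genes were higher in hypoxic neuroblasts, 3 of 32 and 12 adjusted over the list alone, with Nusap1 (1.50 ± 0.22), Ccna2 (1.20 ± 0.22) and Top2a (1.10 ± 0.22). The cell cycle median was 0.44 (list adjusted p = 4.3e-10, and adjusted p = 0.0351 with an estimated correlation). Macrophage markers were lower, 9 of 15 and 10 adjusted over the list alone, with C1qc (-2.13 ± 0.23) and Tyrobp (-2.28 ± 0.30). The macrophage median was -2.13 (list adjusted p = 5.3e-24, and adjusted p = 0.0351 with an estimated correlation). Glial markers were higher, with Gpm6b (2.24 ± 0.38) passing among 13, 8 adjusted over the list alone, and S100b at 1.94 ± 0.41. The glial median was 0.62 (list adjusted p = 1.5e-05, and adjusted p = 0.0351 with an estimated correlation). Of 11 endothelial markers Cldn5 was lower, and 4 adjusted over the list alone, with Emcn at -1.72 ± 0.41. The endothelial median was -0.30 (-0.16 without hypoxic glomus replicate 2, list adjusted p = 5.12e-05, and adjusted p = 0.236 with an estimated correlation).

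In the other lists of this comparison, limma passed Dbh of 13 catecholamine genes, with 2 higher and 1 lower adjusted over the list alone (list adjusted p = 0.204). It passed Scn9a of 20 ion channels, with 1 and 1 adjusted over the list alone (list adjusted p = 0.362), and 0 genes elsewhere. The counts at an unadjusted p under 0.05 were 7 of 26 neuroblast genes, 4 higher adjusted over the list alone (list adjusted p = 0.227), with Tubb2b at 1.27 ± 0.30 and Stmn2 at 0.77 ± 0.20. Of 22 immediate early genes 7 had such a p, 5 lower adjusted over the list alone, and the median was -0.20, -0.13 without hypoxic glomus replicate 1 and -0.43 without replicate 4 (list adjusted p = 4.7e-05, and adjusted p = 0.195 with an estimated correlation). Of 22 dense-core granule genes 5 had such a p, with a median of -0.25 (list adjusted p = 0.000321, and adjusted p = 0.266 with an estimated correlation). Of 20 endoplasmic reticulum stress genes 3 did, 2 lower adjusted over the list alone, with a median of -0.22 (list adjusted p = 0.000309, and adjusted p = 0.236 with an estimated correlation). Of 15 oxygen sensing genes 4 had such a p, with Epas1 at -0.64 ± 0.20 and a list median of -0.17, -0.26 without hypoxic neuroblast replicate 3 or 4 (list adjusted p = 0.0436, and adjusted p = 0.161 with an estimated correlation). Of 28 other HIF targets 5 did, 3 lower adjusted over the list alone, with a median of -0.17, -0.11 without hypoxic glomus replicate 2 and -0.10 without hypoxic neuroblast replicate 2 (list adjusted p = 0.0139, and adjusted p = 0.198 with an estimated correlation). Peripheral neuron markers had a median of 0.19, 0.09 without hypoxic glomus replicate 2 (list adjusted p = 0.0248, and adjusted p = 0.195 with an estimated correlation), with 3 of 15 at an unadjusted p under 0.05 and 3 higher adjusted over the list alone. The lists without a camera call were those of transcription factors (1 of 14 at an unadjusted p under 0.05), glycolysis (3 of 15, 1 higher and 1 lower adjusted over the list alone), oxidative phosphorylation (2 of 47) and ribosomal proteins (0 of 35). The others were those of receptors (5 of 29), HNK-1 (0 of 7), pericytes (1 of 10, 1 higher adjusted over the list alone), fibroblasts (0 of 14), T and NK cells (2 of 15, median 0.06, -0.04 without hypoxic neuroblast replicate 1, and mean -0.003), neutrophils (0 of 11) and erythroid cells (1 of 6). The oxygen sensing call also ended after median centring (0.0625) and quantile normalization (0.0749) and that of HIF targets after quantile normalization (0.118), which gave one to the neuroblast list (0.0355). B3gat1 differed by 0.31 ± 0.29 (adjusted p = 0.72), Chst10 by 0.48 ± 0.28 and Th by -0.98 ± 0.39 (adjusted p = 0.368).

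Without hypoxic neuroblast replicate 1 the camera calls ended for dense-core granules (adjusted p = 0.0537, median -0.12), endoplasmic reticulum stress (0.0533, -0.07), oxygen sensing (0.165, -0.10) and other HIF targets (0.173, -0.08), and the neuroblast list passed (0.000208, median 0.21), while the call of oxygen sensing also ended without normoxic glomus replicate 1 (0.051) or hypoxic glomus replicate 3 (0.067) or 4 (0.067), and that of peripheral neurons without hypoxic glomus replicate 2 (0.0622) or 4 (0.0529) or hypoxic neuroblast replicate 2 (0.0798). Leaving out 1 array ended the calls of Top2a (9 of the 16 fits, adjusted p up to 0.14 over all alternatives), Ccna2 (5, 0.0835) and Scn9a (5, 0.107), and the count was 151 after quantile normalization and 25 in a fit of the 8 arrays compared.

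The interaction asks where the response to hypoxia differed between the populations. Ntng1 (probe 17750713), an axon guidance gene, went from 5.93 ± 0.48 to 2.83 ± 0.12 in neuroblasts and from 2.76 ± 0.28 to 3.04 ± 0.30 in glomus cells (-3.38 ± 0.32, adjusted p = 0.000166). Kcnd2 (-3.36 ± 0.42), Cdh7 (-3.18 ± 0.42), Sctr (-3.06 ± 0.38) and Scn9a (-2.71 ± 0.40) were likewise negative. In normoxic glomus cells all 5 lay under the array median of 4.51, with Ntng1 under the first quartile of 3.21, which limits the fall that could be measured there. Lgr5 (probe 17835844) rose from 5.46 ± 0.64 to 8.02 ± 0.29 in neuroblasts and was 8.86 ± 0.06 and 9.08 ± 0.23 in glomus cells (2.33 ± 0.35, adjusted p = 0.0123). The mitotic genes Depdc1 (2.35 ± 0.38) and Nusap1 (1.82 ± 0.30), Nav2 (1.66 ± 0.30) and the potassium channel gene Kcnk3 (1.60 ± 0.28) were shifted upward in neuroblasts relative to glomus cells. By limma 24 probes passed, 8 positive and 16 negative, all of at least 2-fold, with 2015 at an unadjusted p under 0.05. The counts were 0 positive and 11 negative after median centring, 15 and 14 after quantile normalization, 13 and 12 without hypoxic neuroblast replicate 1 and 18 and 17 without normoxic neuroblast replicate 3.

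The cell cycle list was shifted upward in neuroblasts, with a median of 0.46 and 1 of 32 genes passing, Nusap1, and 10 adjusted over the list alone (list adjusted p = 8.99e-11, and adjusted p = 0.0708 with an estimated correlation), while Pbk stood at 2.11 ± 0.46 (adjusted p = 0.113). The neuroblast and immature neuron list was shifted downward, with a median of -0.69, -0.38 without hypoxic neuroblast replicate 1 (list adjusted p = 2.39e-05, and adjusted p = 0.366 with an estimated correlation). Limma passed 0 of its 26 genes, 2 adjusted over the list alone and 12 at an unadjusted p under 0.05, with Sox4 at -1.35 ± 0.28. The immediate early list was shifted downward as well, with a median of -0.64 (list adjusted p = 7.23e-08, and adjusted p = 0.174 with an estimated correlation), 0 of 22 genes passing by limma, 6 adjusted over the list alone and 9 at an unadjusted p under 0.05, with Fosb at -1.44 ± 0.38 and Nr4a2 at -1.47 ± 0.38. The other 21 lists had no camera call, and in them limma passed Kcnk3 and Scn9a alone. The counts at an unadjusted p under 0.05 were highest for receptors (8 of 29, 3 lower adjusted over the list alone), ion channels (6 of 20, 2 higher and 3 lower), transcription factors (4 of 14, 2 lower), macrophage markers (4 of 15, 3 lower), catecholamine genes (4 of 13, 0) and oxidative phosphorylation (4 of 47, 0). Adjusted over the list alone, 1 HIF target was lower and 1 oxygen sensing and 1 erythroid gene higher. The oxidative phosphorylation list (adjusted p = 0.00537 and 0.000175) and the macrophage list (0.00478 and 0.0164) passed after quantile normalization and without hypoxic neuroblast replicate 1. Median and mean differed in sign for transcription factors (0.02 and -0.14) and HNK-1 genes (0.04 and -0.07), and the test of dense-core granule and neutrophil genes was toward lower values with medians of 0.00 and 0.03. With 1 array left out these medians ran from -0.12 to 0.08 for transcription factors, -0.16 to 0.20 for HNK-1 genes, -0.07 to 0.12 for dense-core granule genes and -0.13 to 0.20 for neutrophil genes. Th differed by -0.65 ± 0.55, Epas1 by -0.39 ± 0.28, B3gat1 by -1.05 ± 0.42 and Chst10 by 0.44 ± 0.39, none of which passed.

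The interaction count of 24 was 11 without normoxic glomus replicate 2 or normoxic neuroblast replicate 4, 12 without normoxic glomus replicate 3 or 4, and 13 without hypoxic glomus replicate 2 or 4. Leaving out 1 array ended the calls of Nav2 (14 of the 16 fits, adjusted p up to 0.146 over all alternatives), Kcnk3 (13, 0.12), Nusap1 (8, 0.1) and Depdc1 (6, 0.0718), and median centring that of Lgr5 (0.0533).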

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

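The tests of quantile normalization, of hypoxic neuroblast replicate 1 for the counts, of a batch, of a larger share of dividing macrophages and of a lower share of the main cell type were chosen after the result was seen, as was the array left out for the cell cycle list, and the other tests here before.

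Genes that passed the interaction test of hypoxia and population included the axon guidance gene Ntng1 and ion channel genes. The hypoxia difference in neuroblasts minus that in glomus cells was -3.38 for Ntng1, -3.36 for Kcnd2, -3.18 for Cdh7, -3.06 for Sctr and -2.71 for Scn9a. These 5 genes lay at 2.76 (Ntng1) to 4.48 (Sctr) in normoxic glomus cells, under the array median of 4.51, so a fall there had little room and their values do not show that glomus cells responded differently. It was 2.35 for Depdc1, 2.33 for Lgr5, 1.82 for Nusap1, 1.66 for Nav2 and 1.60 for Kcnk3. Among the lists the same difference was 0.46 for the cell cycle, -0.69 for neuroblast and immature neuron genes and -0.64 for immediate early genes, each past camera's threshold at the preset correlation and not with an estimated one (adjusted p = 0.0708, 0.366 and 0.174). Kcnd2 and Cdh7 also had 1 array far from the other 3 of a group, at 3.61 in normoxic glomus replicate 3 (others 4.45 to 4.52) and at 6.57 in normoxic neuroblast replicate 1 (others 7.78 to 7.88).

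Single arrays lay far from the other 3 of their group, by a gap that filled most of the group's range, in 30 of 515 groups of 4 values, where chance flags about 1 in 20 groups. Genes of hypoxic glomus arrays were Tac3 (10.84 in replicate 1, others 10.18 to 10.25), Slc6a2 (3.79 in replicate 2, others 4.94 to 4.96), Npy (8.99 in replicate 2, others 9.33 to 9.34), Tbx20 (9.44 in replicate 3, others 9.12 to 9.15), Tyrobp (6.06 in replicate 3, others 7.07 to 7.19), Chst10 (5.09 in replicate 4, others 4.24 to 4.34) and Cdkn3 (5.74 in replicate 4, others 7.59 to 7.96). Genes of normoxic glomus arrays were Gsn (7.18 in replicate 1, others 6.40 to 6.50), Sap18 (5.48 in replicate 1, others 7.07 to 7.32), Cd3g (4.36 in replicate 1, others 4.79 to 4.85), Nav2 (5.57 in replicate 1, others 6.26 to 6.33), Cdk1 (3.97 in replicate 2, others 3.82), Ndufa4l2 (11.70 in replicate 3, others 11.34 to 11.40) and Adm (11.57 in replicate 4, others 11.22 to 11.26). In neuroblasts they were Cd4 (4.05 in normoxic replicate 1, others 4.13 to 4.14), Slc2a3 (6.49 in hypoxic replicate 1, others 8.65 to 9.04), Cks2 (8.43 in hypoxic replicate 4, others 8.71 to 8.74) and Depdc1 (6.11 in hypoxic replicate 4, others 5.61 to 5.69).

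The mean over a list's genes stood apart in the same way on 10 arrays or lists. Hypoxic neuroblast replicate 1 did so for catecholamine genes (6.97, others 7.66 to 7.76), ion channels (5.95, others 6.22 to 6.27), the cell cycle (6.12, others 6.58 to 6.66) and endothelial markers (5.11, others 4.83 to 4.86). The others were catecholamine genes in hypoxic glomus replicate 3 (7.82, others 7.46 to 7.50), oxygen sensing in normoxic neuroblast replicate 3 (7.57, others 7.43 to 7.45), glycolysis in normoxic glomus replicate 4 (7.44, others 7.40), oxidative phosphorylation in hypoxic glomus replicate 1 (9.66, others 9.55 to 9.56), ribosomal proteins in normoxic glomus replicate 2 (9.52, others 9.30 to 9.32) and macrophage markers in normoxic neuroblast replicate 1 (4.76, others 4.16 to 4.24).

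No other of 35 splits of the 8 arrays reached the real count, too few splits to exclude chance. It was 555 against at most 2 for the populations in normoxia, 86 against 3 in hypoxia, 5744 against 2 for hypoxia in glomus cells and 9755 against 54 in neuroblasts. For the interaction it was 24 against at most 0 in the other 99 of 100 regroupings.

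Between hypoxic and normoxic arrays 5744 probes passed in glomus cells and 9755 in neuroblasts. A difference in the overall distribution of values does not account for the count, since 4705 probes passed in glomus cells after quantile normalization, nor does the array that stands apart, since 8074 passed in neuroblasts without it. Separate preparation or hybridization of hypoxic and normoxic arrays cannot be told apart from hypoxia, since no label gives a batch. The first component, with 42.88% of the variance, parts the oxygen conditions, which either would do, so it decides nothing. The response to hypoxia stays open beside it.

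The cell cycle list rose on hypoxic arrays of both populations. A general rise of dim probes would move random lists of the same level alike, but the neuroblast median of 1.37 lay at percentile 100 of 10000 such lists (99th percentile 0.46). Without hypoxic neuroblast replicate 1 the median was 1.51. A larger share of dividing macrophages would raise their markers at least as much as the list. In neuroblasts the mean of the list rose 1.22 ± 0.29 beyond that of the markers, and 0.72 ± 0.33 beyond it among the 17 and 5 genes above the array median in normoxia. The latter value has a wide error and rests on 5 markers. The values thus argue against a larger share in neuroblasts without excluding it. In glomus cells it rose 0.16 ± 0.50 beyond it, so there a larger share cannot be told apart from division of the sorted cells. Macrophages of which a larger part divided, with or without a larger share, were not tested in either population. Division of the sorted cells is a biological hypothesis, and a batch shared with the oxygen condition may still contribute in both.

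Macrophage markers were lower on neuroblast than on glomus arrays. A lower share of the main cell type in the glomus sort would move all other types alike. Endothelial markers did move with the macrophage markers, at -0.80 against -1.48, but fibroblast markers differed by 0.72 (0.18 without normoxic neuroblast replicate 2), pericyte markers by 0.38 and glial markers by 0.24. The fibroblast call ended without that array (adjusted p = 0.112) and with an estimated correlation (adjusted p = 0.336). The fibroblast mean nonetheless parted from the macrophage mean by 2.12 ± 0.62, and by 1.57 ± 0.37 without that array. Such a lower share would not give this alone. Fibroblasts carried in the neuroblast sort could offset it, so that share stays open. A lower share of the main type that brings macrophages and endothelial cells alone was not tested. A varying share of macrophages in the HNK-1 negative sort is a candidate explanation, since their markers had a mean pairwise correlation of 0.74 within groups over the 8 glomus arrays (99th percentile of random lists 0.14), and the gate on HNK-1 does not remove them. Of the 15 markers 0 are in another list and 13 lay above the array median in normoxic glomus cells, with Cd74 at 8.30, C1qa at 7.42, Lyz2 at 6.88 and Fcer1g at 6.65, against 5 in normoxic neuroblasts. Expression of these genes by the sorted glomus cells stays open as untested.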

How the results depend on the processing

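The settings were chosen before the data were examined, except the counts of list genes named above. No gene or list that passed changed its direction. The balance of higher and lower probes did turn for hypoxia in neuroblasts, from 5596 and 4159 to 1826 and 5464 with median centring, 3278 and 3701 with quantile normalization, 3156 and 4224 without the dimmer 50% of probes, 3000 and 3262 with only the arrays compared and 3448 and 3576 with the probes of a gene averaged. It also turned at 2-fold (1688 and 2563) and at an adjusted p under 0.01 (2376 and 2819). It turned under some settings for the other 4 counts too. Over all settings the percent of higher probes ran from 26.6 to 57.3 for hypoxia in glomus cells (49.7 as reported), 25 to 60.4 for hypoxia in neuroblasts (57.4), 48.1 to 60.4 and 28 to 60.5 for the populations in normoxia (54.6) and hypoxia (48.8), and 0 to 52 for the interaction (33.3). Some medians of lists without a call changed sign. The counts for hypoxia in each population stayed within 1.5 times under median centring, quantile normalization, the intensity trend, leaving out the dimmest 25% of probes, the replicate block, averaging the probes of a gene and leaving out any 1 array, and the correlations moved by less than their standard error under each of these that was run on them. With median centring the interaction count was 11, with quantile normalization the count for the populations in hypoxia was 151, and without the dimmer 50% of probes the correlations were 0.856 for the hypoxia differences and 0.458 for the population differences; the cause was not tested. With array weights the counts were 1081 (populations in normoxia), 9490 (hypoxia in glomus cells) and 83 (interaction). Hypoxic neuroblast replicate 1 is in neither of the first 2 comparisons, yet without it they gave 763 and 7232 (555 and 5744 as reported). It can enter them only through the spread that the 4 groups share. Whether the weights act in the same way was not tested. Fitting only the arrays compared gave 578 and 25 for the populations in normoxia and hypoxia and 7435 and 6262 for hypoxia in glomus cells and neuroblasts, and the cause was not tested. The threshold of at least 2-fold, stricter by construction, gave 2760 and 4251 for hypoxia in glomus cells and neuroblasts, and an adjusted p under 0.01 gave 282, 35, 3218, 5195 and 5 for the populations in normoxia and hypoxia, hypoxia in glomus cells and neuroblasts, and the interaction. Leaving out 1 array in turn gave 347 to 763, 59 to 119, 4096 to 7232, 7404 to 10826 and 11 to 35 for these counts, with normoxic glomus replicates 3 (348) and 4 (347) and normoxic neuroblast replicate 1 (353) moving the first by more than 1.5 times, and 0.78 to 0.812 and 0.317 to 0.385 for the correlations. With the replicate number as a block the count for the populations in hypoxia was 130, and the cause was not tested. Replicate numbers were not used as pairs, since the labels do not pair them. Residual correlations of the 16 pairs ran from -0.105 to 0.205 and 6 of 16 arrays matched their own number best.

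Over the 24 lists and 5 comparisons, 40 lost and 0 gained a call with an estimated correlation, 17 lost and 12 gained one with fry, 1 and 1 with median centring, 4 and 5 with quantile normalization, 2 and 7 with array weights and 0 and 3 with the block. Of the 207 calls of named genes, 184 were kept under each alternative run on them and 23 were lost under at least 1, of which 21 were lost by leaving out 1 array. Alternatives that need detection p-values, scanner files or slide numbers, such as another background correction or a block for the slide, were not run. None of these came with the values used here, so signal over background could not be measured. A check on gene length was not possible.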

Other observations

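Families of genes with a shared symbol prefix were tested after the data had been seen, 208 of them, with camera. Whether gene length or separate preparation of hypoxic arrays moved them was not tested. Mitochondrial ribosomal protein genes rose in hypoxia in both populations. Of 45 Mrpl genes (large subunit) 25 rose and 0 fell in glomus cells (median 0.84, adjusted p = 3.57e-08, and adjusted p = 0.385 with an estimated correlation) and 28 rose and 0 fell in neuroblasts (median 0.91, adjusted p = 2.74e-07, and adjusted p = 0.391 with an estimated correlation). Of 27 Mrps genes (small subunit) 18 rose and 0 fell in glomus cells (median 0.86, adjusted p = 0.276 with an estimated correlation), and 17 rose and 0 fell in neuroblasts (median 1.00, adjusted p = 0.364 with an estimated correlation). Of 114 genes with the prefix Rpl, which holds cytosolic large subunit genes and many related copies, 47 rose and 2 fell in glomus cells (median 0.51, adjusted p = 9.25e-10, and adjusted p = 0.0722 with an estimated correlation), and 56 rose and 2 fell in neuroblasts (median 0.56, adjusted p = 1.79e-06, and adjusted p = 0.151 with an estimated correlation). Of 14 Ndufb genes 10 rose in each population and of 12 Ndufa genes 10 in glomus cells (adjusted p = 0.183 to 0.259 with an estimated correlation). The medians of these families were positive after quantile normalization too.

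Of the 15 families with the smallest p in hypoxic neuroblasts, 6 kept the call with an estimated correlation, and the median of each fell. Of 46 Usp genes, which remove ubiquitin from proteins, 27 fell and 1 rose (median -0.84, adjusted p = 7.16e-12, and adjusted p = 0.039 with an estimated correlation). Of 43 Map genes, a prefix shared by microtubule-associated proteins and MAP kinases, 23 fell and 0 rose (median -0.62, adjusted p = 1.91e-08, and adjusted p = 0.039 with an estimated correlation). Of 13 Kdm genes, which remove methyl groups from lysines, many on histones, 11 fell and 0 rose (median -1.03, adjusted p = 0.039 with an estimated correlation). Of 11 Mtmr genes, phosphoinositide phosphatases, 9 fell and 0 rose (median -1.22, adjusted p = 0.039 with an estimated correlation), and of 25 Tbc genes, regulators of Rab proteins, 14 fell and 1 rose (median -0.86, adjusted p = 0.039 with an estimated correlation). Of 39 Zbtb zinc finger genes 14 fell and 2 rose (median -0.51, adjusted p = 0.0433 with an estimated correlation). In hypoxic glomus cells 7 of 13 Kdm genes fell (median -0.72, adjusted p = 0.0516 with an estimated correlation), 14 of 25 Tbc genes (median -0.78, adjusted p = 0.0516), 16 of 43 Map genes (median -0.38, adjusted p = 0.0521), 19 of 46 Usp genes with 2 rises (median -0.40, adjusted p = 0.0885) and 6 of 11 Mtmr genes (median -0.82, adjusted p = 0.0722). Further families among the 15 with the smallest p in a population had a lower median, without a call with an estimated correlation (adjusted p = 0.0515 to 0.231). They were Vps (17 of 30 fell, 1 rose), Ppp (33 of 75, 9 rose), Dhx (10 of 15), Zfp (63 of 242, 15 rose) and Dcaf (8 of 13) in neuroblasts, and Arhgef (8 of 19, 1 rose), Ppp (24 of 75), Vps (11 of 30, 1 rose), Zbtb (9 of 39) and Stk (8 of 21) in glomus cells. Between the populations in normoxia, 4 of 11 Pcdh genes, neuronal adhesion molecules, were higher in neuroblasts and 0 lower (median 0.41, adjusted p = 0.000127, and adjusted p = 0.379 with an estimated correlation). The medians of these families kept their signs after quantile normalization.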
